A study of Homo sapiens with 8 samples.

How the data were processed

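RNA from 4 established human renal carcinoma cell lines (ACHN, CAKI2, A498 and CAKI1), which the submitters describe as clear cell lines, was measured on 8 oligonucleotide arrays. Each line contributed 1 array of cells treated for 24 h with 75 nM A939572, an inhibitor of stearoyl-CoA desaturase, and 1 array of cells given the solvent DMSO. Per the labels' protocols, total RNA was reverse transcribed and in vitro transcribed into biotin-labelled cRNA. The deposited values are intensity signals, 1 per probe set, on a linear scale. The program and settings with which the authors summarized the probes into signals are not given in the sources used here. The values themselves show that each array had been scaled by the authors to the same level: the mean signal after trimming 2% of the probe sets at each end lay between 500.067 and 500.073 on the 8 arrays. Present or absent calls and scan dates were not used here. The table held 54675 probe sets, and every column of sample values in it was used.

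Signals were transformed as log2(signal + 16). The offset keeps dim probe sets from giving large differences and understates the change of dim genes. Array medians on this scale ran from 6.40 to 6.64, a spread above the 0.1 set beforehand as the limit, so the arrays were quantile normalized after 62 control probe sets had been left out. Of the remaining probe sets, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 were unnamed in the table used. Only those with 1 symbol were assigned to a gene, and 41037 of them were matched through the Entrez ID to a current symbol in a table of the GRCh38.p14 annotation, which served for names only. Each gene was represented by its probe set with the highest mean over all 8 arrays. Genes whose mean lay at or above 6.41, the median of all probe sets, were tested, which left 12093 of 19775 genes. Probe sets of a gene can measure different transcripts, and a probe set can match near-identical paralogs. The values of CXCL2, CXCL3 and CD24 are uncertain for that reason.

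The comparison of A939572 with DMSO used limma (version 3.58.1 in R 4.3.3) with lmFit and eBayes with a mean-variance trend, 2-sided, and Benjamini-Hochberg adjustment at 0.05. The cell line entered as a block, since each treated array has its control in the same line, as the submitters' design states. The pairing was checked on the data: across genes, the deviations of the 2 arrays of a line from their group means correlated at 0.818 to 0.864, and no array correlated above -0.0303 with an array of another line in the other group. The 4 lines are the replicates. The labels do not state separate cultures within a line. A gene's p-value therefore rests on the spread between these lines, with its variance moderated towards that of genes of similar mean. The degrees of freedom, residual plus prior, were 9.28. An exact test on 4 pairs cannot give a 2-sided p below 0.125, and the number of arrays limits the precision, with a median SE of 0.17 for a log2 difference. All errors given with log2 differences are SDs over the 4 lines.

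Gene lists for lipid metabolism, stress responses, the cell cycle, energy metabolism, inflammation, cell type markers and reference genes were fixed before the data were examined, as were the comparisons, the tests and most alternatives. They named 638 genes, of which 517 were tested and 63 were not analysed here for lack of a probe set with 1 symbol. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 29 lists that had at least 3 tested genes. The SCD enzymes and the endothelial markers had 2 tested genes each and were not tested as lists. Member counts were taken over all genes tested and also adjusted over the list alone. For each line, where 1 array stands against 1 and no test is possible, a list's median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A further 11 lists were drawn up after the results had been seen and are reported as such.

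The genes named were chosen by a rule fixed beforehand. It takes SCD and SCD5, and the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold that moved the same way in all 4 lines. For each list it takes up to 4 members past the threshold with the largest change, or up to 2 with the smallest p where none passed. It also takes the 5 largest changes each way within each line, and the 10 largest each way among genes changed at least 1.5-fold in all 4 lines. Other genes named are said to have been chosen after their values were seen.

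The fit was tested on simulated data built from the means and variances of the 12093 genes, with 200 genes changed. It recovered 47.8% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 97% of those with a log2 change of 2. Of 170 genes called, 21 (12.4%) were false, above the nominal share. That led to 20 further simulations of each of 2 kinds. The mean false share was 8.2% with 200 changed genes and 3.39% with 3706 changed genes, the number called in the data. Simulated changes were at least 1.5-fold and the genes varied independently, so neither share estimates that of the data. Camera called 0 of 50 unchanged random lists. The simulated genes varied independently, so this does not test the preset correlation in lists whose genes move together. The estimated correlation was 0.602 in the G1/S list and 0.608 in the G2/M list.

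Alternatives covered the block, the filter, the choice of probe set, the scaling, the offset, the variance model, the threshold, the list test and each line left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.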

Results

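The series compared cells treated with A939572 with cells given DMSO in 4 renal carcinoma lines, 4 arrays against 4. A939572 inhibits stearoyl-CoA desaturase 1, the enzyme that turns saturated fatty acids into monounsaturated ones. ACHN, CAKI2, A498 and CAKI1 are established human kidney cancer lines. The design asked which expression changes accompany 24 h of the drug at 75 nM and how far the lines share them. Signals on the 8 arrays had medians between 68.4 and 84.0 units. Differences are log2 values, A939572 minus DMSO, with the SD over the 4 lines.

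SCD, the gene of the inhibited enzyme, was lower in treated cells, with a log2 difference of -0.52 ± 0.34 (SD, n = 4 lines; limma adjusted p = 0.0121, Benjamini-Hochberg). In this brightest probe set it had -0.93 in ACHN, -0.10 in CAKI2, -0.49 in A498 and -0.55 in CAKI1. Its other 3 bright probe sets had -0.92 ± 0.34, -0.11 ± 0.28 and -0.42 ± 0.48, and the last 2 had 0.11 and 0.03 in CAKI2, with 0.06 in A498 in the former of them. The drug acts on the enzyme, so the transcript is no check of the labels. SCD5, a related desaturase, had a log2 difference of 0.31 ± 0.28 and did not pass (adjusted p = 0.302), and its probe sets disagreed: the next brightest gave -0.62 ± 0.24. The call of SCD was lost without the cell line as a block (adjusted p = 0.454) and without the variance trend (0.0622).

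The list medians of the unfolded protein response and of NF-kB targets and cytokines lay above 0, and those of DNA replication and mitosis below 0, in every line. ATF3, a stress-induced transcription factor, rose by a log2 difference of 4.02 ± 0.16 or 16.2-fold in its brightest probe set (limma adjusted p = 3.94e-07) and had 2.51 to 3.54 over the lines in the next probe set and 1.94 ± 0.76 in the dimmest. BHLHA15, a transcription factor of secretory cells, rose by 3.79 ± 1.01, the chemokine genes CXCL2, CXCL8 and CXCL3 by 3.78 ± 1.35, 3.63 ± 0.38 and 3.10 ± 0.37, and the cytokine IL6 by 3.04 ± 0.72. FOS rose by 3.36 ± 0.83, the endoplasmic reticulum cochaperone DNAJB9 by 3.23 ± 0.37, the calcineurin regulator RCAN1 by 3.04 ± 0.67 and DDIT3, which encodes CHOP, by 2.98 ± 0.66. With the mean of all probe sets the log2 difference of ATF3 was 2.98, below the log2 difference of CXCL8 at 3.93, and the log2 difference of RCAN1 was 1.92. CXCL2 had 1.93 ± 0.57 in its next probe set, and the means of BHLHA15 (5.97) and FOS (4.74) in DMSO lay below the 6.41 used as filter, so their sizes are uncertain. At offset 64 the log2 difference of BHLHA15 was 3.03 and the log2 difference of FOS was 2.11. The noncoding transcript MIR181A2HG fell, with -3.44 ± 0.65 (adjusted p = 0.000274). Its mean in treated cells, 4.83, lay below that level too, as did those of SLITRK5 (5.99) and KIFC1 (6.35), given next. At offset 64 the log2 difference of MIR181A2HG was -2.22, the log2 difference of SLITRK5 was -1.53 and the log2 difference of KIFC1 was -1.69. Also lower were lamin B1 (LMNB1) at -2.42 ± 0.14 (adjusted p = 2.52e-05), GINS2 at -2.33 ± 0.57, UHRF1 at -2.30 ± 0.64, the kinetochore gene SPC24 at -2.24 ± 0.61, MCM6 at -2.24 ± 0.57, ID1 at -2.23 ± 1.34, the mitotic kinesin KIFC1 at -2.23 ± 0.71, SLITRK5 at -2.13 ± 0.85 and MCM4 at -2.12 ± 0.42. Among these falls ID1 varied most, from -3.34 in ACHN to -0.29 in CAKI1, and without CAKI1 the log2 difference of ID1 was -2.88. With the mean of all probe sets the log2 difference of GINS2 was -1.18, the log2 difference of SPC24 was -1.26 and the log2 difference of MCM4 was -1.52. With probe sets that can match several transcripts left out, GINS2 had -0.19 (adjusted p = 0.607).

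**Figure D1:**
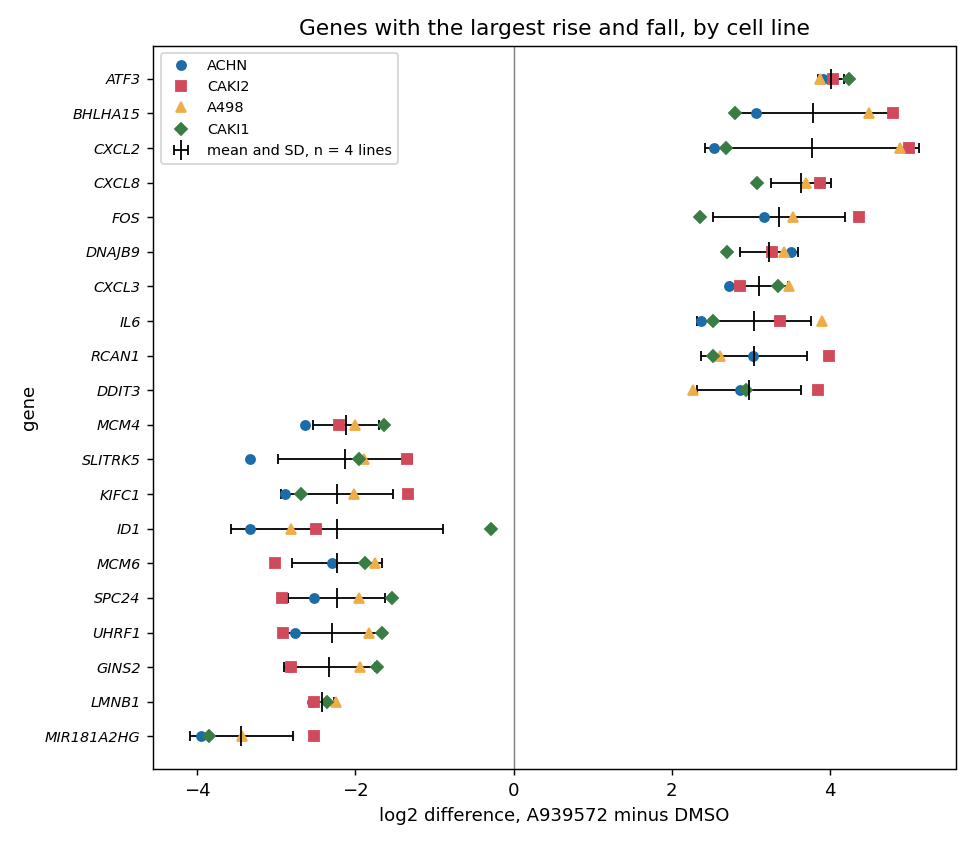
Log2 difference (A939572 minus DMSO, x axis) of the 10 genes with the largest rise and the 10 with the largest fall (y axis); symbols are the 4 cell lines, and bars are the mean and SD over the lines. ATF3 lies between 3.88 and 4.24 in all 4 lines, while ID1 spreads from -3.34 to -0.29.

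In total 3706 of 12093 genes (30.6%) passed the threshold in limma, 1778 higher and 1928 lower, and 3610 of them moved the same way in 4 of 4 lines. At least 2-fold changes were seen for 445 of the genes that were higher and 437 of those that were lower. Without the cell line as a block the fit called 38 genes higher and 29 lower. Centring each array on its median in place of quantile normalization gave 2163 higher and 1545 lower, 58.3% higher against 48% in the quantile normalized values.

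Control probe sets differed with treatment on the same arrays. The ratio of the 3′ to the 5′ probe set of ACTB was 2.12 to 2.33 in DMSO and 3.02 to 4.22 in treated cells, a log2 difference of 0.64 ± 0.25, higher in 4 of 4 lines. That of GAPDH differed by 0.08 ± 0.05. Both ACTB control probe sets were lower with treatment in 4 of 4 lines. The log2 difference was -0.78 ± 0.20 for the 3′ and -1.42 ± 0.37 for the 5′ probe set. The 5′ probe set for 28S ribosomal RNA was 5.12-fold higher on average (log2 difference 2.36 ± 0.66), from 2.58-fold in CAKI2 to 6.95-fold in CAKI1, while its middle probe set differed by 0.54 ± 0.29. The spiked hybridization controls differed by 0.08 ± 0.15 and the spiked polyadenylated controls by 0.02 ± 0.19. The 3′ to 5′ difference of the spiked polyadenylated controls was 0.13 ± 0.09 higher with treatment, in 4 of 4 lines. Every gene group below was read from these arrays.

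**Figure D2:**
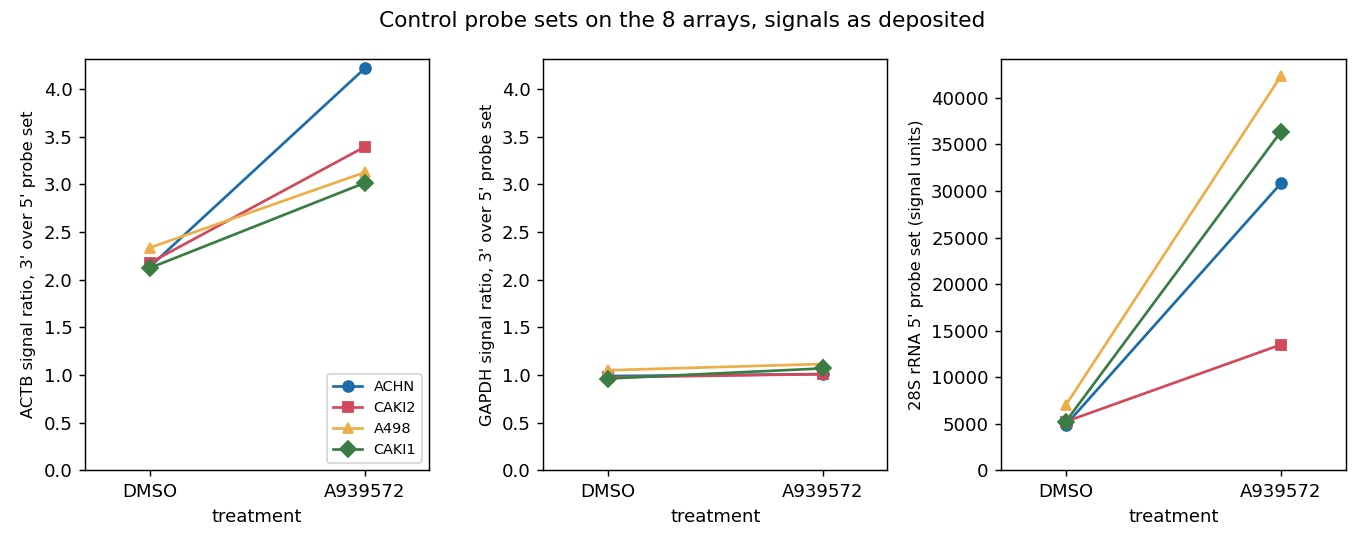
Ratio of 3′ to 5′ probe set signal for ACTB and GAPDH, and signal of the 28S ribosomal RNA 5′ probe set (y axes, linear, signals as deposited), for DMSO and A939572 (x axes); each line joins the 2 arrays of a cell line. The ACTB ratio lies at 2.12 to 2.33 in DMSO and 3.02 to 4.22 after treatment.

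Genes of the unfolded protein response of the endoplasmic reticulum rose together. Among targets of ATF6 and XBP1, which supply folding and degradation factors, 26 of 31 tested rose and 0 fell, with a list median of 1.07. DNAJB9 led them, followed by SELENOS (1.92 ± 0.27), HERPUD1 (1.91 ± 0.61) and the chaperone HYOU1 (1.88 ± 0.31). Of the PERK-ATF4-CHOP branch, which couples translation control to amino acid supply and cell death, 26 of 35 rose and 0 fell, with a median of 0.98. ATF3 and DDIT3 were followed there by GADD45A (2.17 ± 0.26) and STC2 (2.10 ± 0.92). Both lists passed camera in limma, with adjusted p = 8.14e-18 and 4.13e-11. Each had an adjusted p = 0.306 with an estimated correlation, and no list of the 29 passed in that setting. The fatty acid synthesis and immediate early lists lost their calls too, though their estimated correlations (0.00968 and -0.00432) lay below the preset 0.01. With fry, another list test in limma, adjusted p was 0.00917 for the ATF6 and XBP1 list and 0.00955 for the PERK branch. Fry asks whether a list's genes shift at all, and camera whether they shift more than other genes. With 30.6% of all genes past the threshold, passing fry is therefore no check of camera's calls. Adjusted over the list alone, 28 of the ATF6 and XBP1 targets were higher and 0 lower, and 26 of the PERK branch were higher and 2 lower. In the treated arrays on which these genes rose, the ACTB 3′ to 5′ ratio was also higher, as given above.

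Inflammatory and immediate early genes rose as well. Of 20 NF-kB targets and cytokines, 11 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.83. In their brightest probe sets CXCL2, CXCL8, CXCL3 and IL6 led them. The list passed camera at the preset correlation (adjusted p = 3.32e-06) but not with an estimated correlation (adjusted p = 0.306). Of 18 immediate early genes and MAPK feedback regulators, 9 rose and 0 fell by either adjustment, all genes or adjusted over the list alone. The median was 0.51 (adjusted p = 4.67e-05, and adjusted p = 0.306 with an estimated correlation). FOS, the phosphatase gene DUSP1 (2.08 ± 0.63), PHLDA1 (1.16 ± 0.80) and JUN (1.13 ± 0.40) changed most in their brightest probe sets. DUSP1 had 0.07 ± 0.96 in its dimmest, and PHLDA1 had 0.63 ± 1.09 in its next, with 2.25 in ACHN and -0.03 to 0.27 in the other lines. In its brightest it had 2.35 in ACHN and 0.65 to 0.95 in the others, and without ACHN the log2 difference of PHLDA1 was 0.77. The NF-kB target that fell, TNFAIP2 (-0.67 ± 0.26), was named after its value was seen. Among 21 p53 targets, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.26, or 0.42 without CAKI2 (adjusted p = 0.00106, and adjusted p = 0.333 with an estimated correlation). SESN2 (1.94 ± 0.24), PMAIP1 (1.70 ± 0.52) and TNFRSF10B (1.17 ± 0.41), the first and last of which are also on the PERK branch list, were ahead of MDM2 (1.00 ± 0.27), and CDKN1A, the canonical p53 target, rose by 0.69 ± 0.16. MDM2 had 0.26 (adjusted p = 0.487), and the list an adjusted p = 0.182, without probe sets that can match several transcripts. The autophagy and lysosome list had 6 of 22 genes higher and 1 lower by both adjustments, all genes or adjusted over the list alone. It had a median of 0.21, or 0.33 without A498 (adjusted p = 0.0393, and adjusted p = 0.333 with an estimated correlation). Its leading genes were WIPI1 (1.62 ± 0.73), GABARAPL1 (1.32 ± 0.50), ATG12 (0.84 ± 0.20) and UVRAG (0.80 ± 0.45), and LAMP2 (-0.40 ± 0.28), named after its value was seen, fell. That call was lost without CAKI1 (adjusted p = 0.053) and in 5 other settings, the estimated correlation included.

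Genes of DNA replication and mitosis fell. Of 31 genes of the G1/S transition and DNA replication, 28 fell and 0 rose, with a median of -1.35 (camera adjusted p = 2.11e-16, and adjusted p = 0.333 with an estimated correlation). In their brightest probe sets GINS2, UHRF1, MCM6 and MCM4 changed most, which serve the replicative helicase or maintenance methylation. Of 30 genes of G2/M and mitosis, 28 fell and 0 rose, with a median of -0.95 (adjusted p = 1.84e-14, and adjusted p = 0.333 with an estimated correlation). TOP2A fell by 1.63 ± 0.44 on the log2 scale, DLGAP5 by 1.55 ± 0.55, KIF11 by 1.55 ± 0.79 and CDK1 by 1.48 ± 0.56. Adjusted over the list alone, the counts were 29 lower and 1 higher for G1/S and 28 lower and 0 higher for G2/M. Among 12 regulators of G1, 3 rose and 2 fell, also when adjusted over the list alone. Cyclin D1 (CCND1) fell by 1.08 ± 0.29 and the inhibitor CDKN1A rose by 0.69 ± 0.16. That list's median was -0.07 and its mean -0.02, while camera ranked it higher (adjusted p = 0.851). With a line left out the median ran from -0.14 to 0.06. These falls, too, were measured on treated arrays with a higher ACTB 3′ to 5′ ratio.

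Transcripts of lipid synthesis fell. Of 18 genes of cholesterol synthesis, 11 fell and 0 rose, with a median of -0.69 (camera adjusted p = 1.01e-05, and adjusted p = 0.306 with an estimated correlation). EBP (-1.66 ± 0.16), ACAT2 (-1.29 ± 0.30), IDI1 (-1.20 ± 0.33) and LSS (-0.94 ± 0.16), enzymes of the sterol pathway, were lowest. Of 15 genes of fatty acid synthesis and desaturation, SCD among them, 9 fell and 0 rose, with a median of -0.52 (adjusted p = 0.00245, and adjusted p = 0.306 with an estimated correlation). The elongase ELOVL6 (-1.06 ± 0.61), ACSS2 (-1.02 ± 0.41), the desaturase FADS2 (-0.91 ± 0.61) and ATP citrate lyase ACLY (-0.83 ± 0.13) were lowest. Counts adjusted over the list alone were the same for both. The glycerolipid and phospholipid list, with 2 of 20 genes higher and 6 lower (2 and 9 adjusted over the list alone), did not pass (adjusted p = 0.13). PCYT2 (-0.73 ± 0.19) and PTDSS1 (-0.73 ± 0.25) of phospholipid synthesis fell there. Of 7 LXR targets 1 rose and 1 fell by both adjustments, all genes or adjusted over the list alone (list adjusted p = 0.468). The cholesterol exporter ABCA1 rose by 1.48 ± 0.38. LPCAT3 fell by 0.78 ± 0.32 in its brightest probe set but had 0.56 ± 0.38 in another. Of 18 genes of fatty acid oxidation and PPAR targets, 1 rose and 3 fell by both adjustments, all genes or adjusted over the list alone (list adjusted p = 0.653). HADH fell by 1.43 ± 0.52, and PLIN2, a lipid droplet protein, rose by 0.71 ± 0.53 in its brightest probe set and had -0.93 ± 0.92 in another. IDI1 is another gene whose probe sets disagreed, at -1.21 ± 0.32 and 0.08 ± 0.25 in the next 2. LSS had -0.20 ± 0.20 in its other bright probe set and, with the mean of all probe sets, -0.29 (adjusted p = 0.26). That setting also ended the calls of FADS2 (-0.56, adjusted p = 0.105), PCYT2 (-0.57, 0.108) and LPCAT3 (-0.11, 0.59). FADS2 lost its call without CAKI2 (adjusted p = 0.0535) or CAKI1 (0.0662), and PLIN2 without ACHN (0.0562) or CAKI1 (0.0626). The fatty acid synthesis call was lost with a stricter filter (adjusted p = 0.0514) and without probe sets that can match several transcripts (0.435).

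Nuclear genes of oxidative phosphorylation fell, 14 of 26 with 0 higher (16 and 0 adjusted over the list alone). The median was -0.36 (camera adjusted p = 6.27e-06, and adjusted p = 0.333 with an estimated correlation). The complex I genes NDUFA2 (-1.03 ± 0.23) and NDUFB3 (-0.84 ± 0.37) were lowest, ahead of SDHC (-0.71 ± 0.32) and CYC1 (-0.55 ± 0.09). SDHC had -0.06 (adjusted p = 0.807) without probe sets that can match several transcripts, and NDUFA2 -0.55 (adjusted p = 0.0849) with the mean of all probe sets. The other lists did not pass camera in the analysis as described. Closest were hypoxia and HIF targets, with 10 of 25 higher and 2 lower (11 and 3 adjusted over the list alone; adjusted p = 0.0539). ADM (1.30 ± 0.64) and LOX (1.22 ± 0.51) rose there. Glycolysis had 2 of 19 higher and 7 lower by both adjustments (adjusted p = 0.0695), with HK2 at 0.93 ± 0.24 and PKM at -0.74 ± 0.13. HK2 had -0.36 ± 0.48 and -0.27 ± 0.60 in its other bright probe sets, and 0.098 (adjusted p = 0.663) with the mean of all probe sets. PKM had -0.26 ± 0.32 in its other. The interferon response had 6 of 21 higher and 1 lower by both adjustments (adjusted p = 0.101), with IFIT2 at 2.22 ± 1.28. NRF2 targets had 5 of 17 higher and 3 lower (7 and 3 adjusted over the list alone; adjusted p = 0.11), with HMOX1 at 2.37, from 1.25 in A498 to 4.48 in ACHN, and SLC7A11 at 1.77 ± 1.25. Fibroblast markers had 0 of 4 higher and 2 lower by both adjustments (adjusted p = 0.0695), COL1A1 at -1.04 ± 0.36 and FBLN1 at -0.86 ± 0.23, and leukocyte markers 0 of 4 either way (adjusted p = 0.672). FBLN1 lost its call without A498 (adjusted p = 0.0669). With no filter on dim genes hypoxia (adjusted p = 0.0183), interferon (0.0293) and glycolysis (0.0341) passed, and with the mean of all probe sets glycolysis (0.0187). With a line left out, hypoxia passed without ACHN (0.00769) or A498 (0.0136), interferon without ACHN (0.00769), glycolysis without CAKI1 (0.0368) and NRF2 targets without CAKI2 (0.0209) or A498 (0.0143). The log2 difference of HMOX1 was 1.66 without ACHN. COL1A1 had -0.11 ± 0.22 in its next probe set. With the mean of all probe sets COL1A1 had -0.42 (adjusted p = 0.161) and FBLN1 -0.51 (0.0763).

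Of 10 reference genes 0 were higher and 3 lower (5 lower adjusted over the list alone), ACTB at -0.75 ± 0.26, HPRT1 at -0.71 ± 0.38 and GUSB at -0.45 ± 0.15, a call lost without ACHN (adjusted p = 0.0747) and with the mean of all probe sets (0.0696). The list did not pass (adjusted p = 0.135), and its median of -0.15 was below 0 under the other 2 scalings also. Ribosomal protein genes had 0 of 19 past the threshold either way and by both adjustments (adjusted p = 0.929). Their median of 0.02 and mean of -0.02 lay on opposite sides of 0, and the median was -0.06 in the values as deposited and -0.04 without ACHN. Counts for the remaining lists were the same over all genes and adjusted over the list alone, except that renal epithelial genes had 3 lower by the latter. Apoptosis regulators had 6 of 23 higher and 5 lower (adjusted p = 0.672), with CASP6 at -1.50 ± 0.08 and PMAIP1 at 1.70 ± 0.52. Heat shock genes had 2 of 12 higher and 1 lower (adjusted p = 0.775), with BAG3 at 0.81 ± 0.26 and HSPE1 at -0.73 ± 0.33. The median of that list was -0.02, while its mean of 0.04 and camera lay above 0, and with a line left out it ran from -0.10 to 0.06. Renal epithelial genes had 3 of 13 higher and 2 lower (adjusted p = 0.831), with OCLN at 1.29 ± 0.32. TGF-beta and mesenchymal genes had 2 of 19 higher and 5 lower (adjusted p = 0.653), with ZEB2 at 1.39 ± 0.23 (0.47 ± 0.47 in its dimmest bright probe set) and SPARC at -0.85 ± 0.28. Ribosome biogenesis had 2 of 18 higher and 2 lower (adjusted p = 0.75), with NHP2 at -0.87 ± 0.26, and RRP12 at 0.95 ± 0.33 in its brightest probe set and -0.07 ± 0.77 in the next. Wnt targets had 1 of 6 higher and 1 lower (adjusted p = 0.64), CCND1 being the lower.

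**Figure D3:**
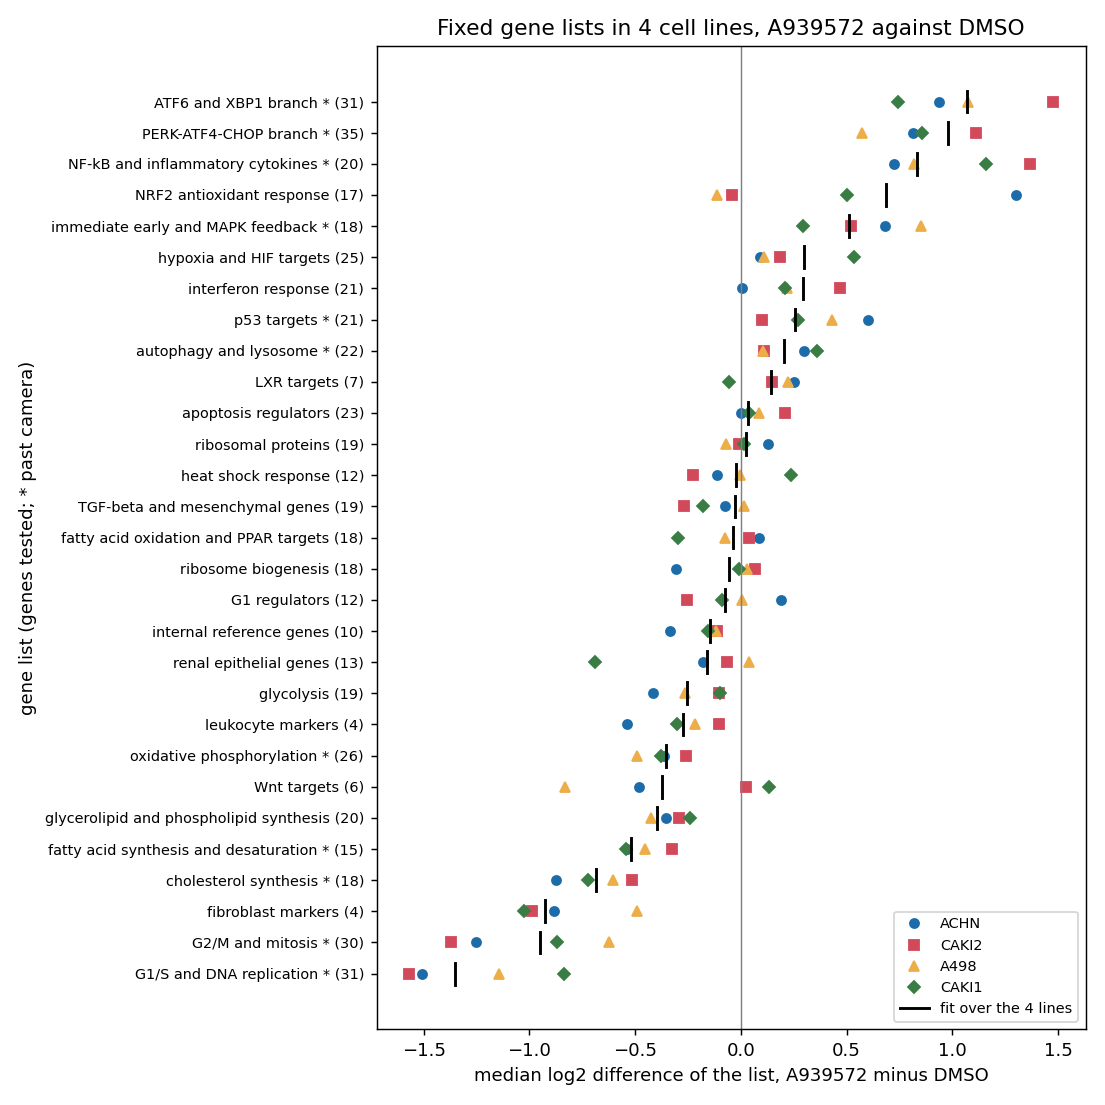
Median log2 difference (A939572 minus DMSO, x axis) of the 29 tested gene lists (y axis, with the number of genes tested; * marks lists past camera at the preset correlation); symbols are the 4 cell lines and black bars the median from the fit over the 4 lines. ATF6 and XBP1 targets lie at 1.07 and G1/S genes at -1.35, with all 4 lines on the same side of 0 in each.

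The response of each line was read as a difference between 2 arrays, with no replicate check. At 1.5-fold, ACHN had 2251 genes higher and 2310 lower, CAKI2 1866 and 2084, A498 1941 and 2080, and CAKI1 1595 and 2023. ATF3, by its brightest probe set, was among the 5 largest rises in all 4 lines. RAB39B (4.89), HMOX1 (4.48), encoding heme oxygenase, and thrombomodulin THBD (4.04) led in ACHN. In CAKI2, CXCL2 (5.00) and BHLHA15 (4.80) led, followed by IL1A (4.58) and FOS (4.36). IL1A had that value in its brightest probe set and -0.06 in the other. FBN2 had 4.73 in A498 and between -0.46 and 0.76 elsewhere, while its other 2 probe sets, both dim, had -1.01 and -0.74 in A498. In CAKI1, CCL20 (3.59), LURAP1L (3.52), TNFAIP6 (3.46) and LCN2 (3.45) followed ATF3. Among the largest falls were ZBED2 in ACHN (-3.95), GAMT (-3.25) and MCM5 (-3.18) in CAKI2, CDH6 in A498 (-3.24) and ADAMTS15 in CAKI1 (-3.25). MIR181A2HG had -3.95 in ACHN, -3.44 in A498 and -3.85 in CAKI1, and -2.53, -2.17 and -2.48 at offset 64. In CAKI2, CXCL2 had 2.67 with the mean of all probe sets and 1.71 without those that can match several transcripts, FOS had 2.77 and the log2 difference of BHLHA15 in CAKI2 was 3.83 at offset 64, and the log2 difference of RAB39B in ACHN was 3.26 at that offset. The log2 difference of CDH6 in A498 was -2.41 with the mean of all probe sets. In CAKI2, GAMT had -1.49 with the mean of all probe sets and MCM5 -1.75 in its other bright probe set, and in CAKI1 ADAMTS15 had -1.95 at offset 64. NRF2 targets had a median of 1.30 in ACHN and 0.50 in CAKI1, at percentiles 100 and 99.97 of matched random lists, against -0.04 in CAKI2 and -0.11 in A498, at 51.13 and 36.01. Whether the lines differ was not tested. ATF6 and XBP1 targets had medians from 0.74 in CAKI1 to 1.48 in CAKI2, and G1/S genes from -1.57 in CAKI2 to -0.84 in CAKI1, beyond all matched random lists in each line.

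The lines shared much of the response. At least 1.5-fold in 4 of 4 lines, 463 genes were higher, led in their brightest probe sets by ATF3, BHLHA15 and CXCL2, and 505 lower, led by MIR181A2HG, LMNB1 and GINS2. Independent lists of the same lengths would share 7.35 and 11.5 genes. CD24 (-2.11 ± 1.07), a surface glycoprotein gene, was the only 1 of the 10 lowest shared genes not among the 10 largest falls above, where ID1 stood. In at least 3 lines 1050 genes were higher and 1207 lower, and 709 genes were higher in at least 1 line and lower in at least 1 other. Across the 12093 genes, which are not independent replicates, the differences of the 6 pairs of lines correlated at Pearson r 0.52 to 0.59 and Spearman rho 0.51 to 0.60. With the mean of all probe sets 308 genes were higher in 4 of 4 lines. The count of shared genes at 2-fold was 117 higher and 93 lower, and without CAKI1 the other 3 lines shared 698 genes that were higher.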

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

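The test of a label swap within a line, the counts over sign patterns, the restriction of the blocked splits to those that part all 4 pairs and the 3 tests on control probe sets were chosen after the results they bear on had been seen; the other splits of the arrays, the other scalings and the comparison of probe sets within genes were set down before their results were known.

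The medians of the PERK and ATF6 lists were above 0 and those of the G1/S and G2/M lists below 0 in all 4 lines, within 3706 genes past the threshold. Among the 8 splits of the arrays that part all 4 pairs, 1, the real split, gave as many genes and the highest other gave 0, which are too few splits for a share under 0.05; the 24 others that can be fitted with the block part 2 pairs only, and the highest of them gave 0. A swap of labels within 1 line would turn that line's response against the others, and the lowest of the 6 correlations between lines was 0.520, which argues against it. The scaling of the arrays is also argued against by the size of the medians. Under 2 other scalings those of the PERK, ATF6, G1/S and G2/M lists lay at least 0.875 from 0. The median of all genes tested ran from -0.0484 to 0.0334 over the scalings. Direction and call were kept in 8 of 8 tests. The 2 other scalings differ by a constant per array, which a comparison of a list with the other genes hardly registers, so the calls add little. Lower RNA integrity in treated cells cannot be told apart from a treatment effect for the rise or the fall: all bright probe sets were higher in 97.1% of the PERK and ATF6 genes with several (33 of 34) and lower in 100% of the G1/S and G2/M genes (30 of 30), but these genes were picked as past the threshold in that direction, so agreement of their probe sets decides nothing.

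Without the block, 2 of the 35 splits gave as many genes as the 67 of the real split, so chance is not excluded in that fit. The other was a split that sets a pair of cell lines against the other pair, with 341 genes, which points to differences between the lines. For the 968 genes changed at least 1.5-fold the same way in all 4 lines, 1 of the 8 sign patterns of the pairs, the real pattern, gave as many, and the highest other gave 30. The 8 patterns are too few for a share under 0.05.

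The control probe sets lay outside the comparisons of genes. The 28S ribosomal RNA 5′ probe set was above its DMSO level by a log2 difference of 2.36 ± 0.66, and the ACTB 3′ to 5′ ratio by 0.64 ± 0.25, in 4 of 4 lines. A difference in hybridization or staining is argued against by the hybridization spikes, which differed by 0.079 ± 0.15. The 3′ to 5′ difference of the spiked polyadenylated controls rose by 0.13 ± 0.09, less than that of ACTB. It was higher in 4 of 4 lines, though by only 9.04e-05 in CAKI2. A difference in amplification and labelling as large as the ACTB rise is argued against for the spikes. A smaller one, or one that differs between transcripts, stays open. A fall of RNA integrity common to all transcripts stays open: the GAPDH ratio differed by 0.0796 ± 0.05, but both GAPDH probe sets are among the brightest and may be saturated, and the treatment cannot be told apart from it. The ACTB 3′ probe set was nearly as bright, with a mean log2 signal of 15.0 in DMSO against 15.4 for that of GAPDH. Saturation may therefore bear on the ACTB ratio as well, since both ACTB probe sets fell with treatment. No biological explanation was tested.

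Of 171 sets of 4 line differences (129 genes, 29 lists and 13 control measures), 4 held a line far from the others, where chance flags about 1 in 20. ACLY had -0.63 in A498 against -0.91 to -0.89 in the other lines. CDKN1A had 0.94 in ACHN against 0.60 to 0.63. ZEB1 had 0.36 in CAKI1 against 0.82 to 0.85. The 28S 5′ probe set had 1.37 in CAKI2 against 2.60 to 2.80. For 3 of the genes named by the rule, 2 lines moved at least 1.5-fold in opposite directions, a difference that was not tested because each line has 1 array per treatment. C21orf58 had 1.37 in CAKI1 and -2.98 in CAKI2, IL1A had 4.58 in CAKI2 and -1.08 in ACHN, and THY1 had 1.11 in CAKI1 and -3.14 in ACHN. The C21orf58 probe set had a mean of 6.63, near the filter of 6.41, and the gene's other probe sets lay below the filter. The values of IL1A hold for its brightest probe set, and without probe sets that can match several transcripts it had -0.06 in CAKI2.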

How the results depend on the processing

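Values as deposited, the setting without probe sets that can match several transcripts (suffix _s_at or _x_at), offsets 1 and 64 for results other than gene counts, and keeping each gene's probe set as chosen on all 8 arrays were decided after the data were seen. The last followed a first run in which the brightest probe set was chosen again in each setting. Chosen again, LPCAT3 had 0.74 without CAKI1 (limma adjusted p = 0.0241) against -0.78, and IL1A in CAKI2 had -0.07 at offset 1 against 4.58, the 2 reversals among 1256 such values. The cause is the switch to another probe set of the gene.

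The counts of genes past the threshold stayed within 1.5 times under the other scalings, offsets, filters, variance models and threshold, and between 1237 and 1500 higher and 1395 and 1567 lower with a line left out. They were 38 higher and 29 lower with no replicate block, where SCD had -0.52 (adjusted p = 0.454) and 86 named genes lost their call, and 3545 higher and 3543 lower with every probe set tested on its own, which tests more items. SCD also lost its call without the variance trend (-0.52, adjusted p = 0.0622); with a line left out it had -0.66 to -0.38 (0.00581 to 0.0464). The block changed no list call. With an estimated correlation camera called 0 lists higher and 0 lower. The lost calls included the fatty acid synthesis and immediate early lists, whose estimates (0.00968 and -0.00432) lay below the preset. Since camera then also uses the residual degrees of freedom, the losses do not measure correlation between genes alone. Fry called 9 lists lower and ended none of camera's list calls, but it does not compare a list with other genes as camera does.

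Without probe sets that can match several transcripts, IDI1 had 0.23, RRP12 -0.074 and IL1A in CAKI2 -0.063, and with the mean of all probe sets PLIN2 had -0.11, each turned from its main direction since the probe sets disagree. Of named genes and lists across settings, 1528 and 484 values kept their call or lack of one, 169 and 19 lost the call and 1 and 15 gained it. A turn of direction was counted only where the main or the other setting passed. Values that passed in neither are among those kept, whatever their direction. Leaving out a line ended calls of 10 named genes without ACHN, 11 without CAKI2, 9 without A498 and 11 without CAKI1, among them FADS2 without CAKI2 (adjusted p = 0.0535) or CAKI1 (0.0662), PLIN2 without ACHN (0.0562) or CAKI1 (0.0626), CDH6 without CAKI2 (0.0585) or A498 (0.0847), FBLN1 without A498 (0.0669) and GUSB without ACHN (0.0747). The NRF2 list passed without CAKI2 (0.0209) or A498 (0.0143), hypoxia without ACHN (0.00769) or A498 (0.0136), interferon without ACHN (0.00769) and glycolysis without CAKI1 (0.0368). With no filter on dim genes hypoxia (0.0183), interferon (0.0293) and glycolysis (0.0341) passed, with the mean of all probe sets glycolysis (0.0187), and with fry LXR targets (0.0192), fatty acid oxidation (0.0192), glycerolipids (0.00854), fibroblast markers (0.00854) and reference genes (0.0341). Fry asks a different question from camera, and the cause of the other changes was not tested.

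Genes at least 1.5-fold higher in every line numbered 308 with the mean of all probe sets and 527 to 698 with a line left out, since fewer lines must share them. At 2-fold, 117 were higher and 93 lower in every line and 323 and 311 in at least 3 lines; the stricter filter left 776 lower in at least 3. Counts per line, higher and lower, were 3867 and 4098 (ACHN), 3437 and 3863 (CAKI2), 3539 and 3671 (A498) and 3198 and 3849 (CAKI1) with no filter, 1401 and 1298, 1171 and 1173, 1143 and 1201, and 936 and 1032 with the stricter filter, and 918 and 977, 773 and 754, 770 and 700, and 570 and 662 at 2-fold. Correlations between lines with no filter, the stricter filter, offset 1 and offset 64 were 0.351, 0.719, 0.538 and 0.631 for ACHN and CAKI2, 0.337, 0.731, 0.512 and 0.623 for ACHN and A498, 0.336, 0.757, 0.534 and 0.654 for ACHN and CAKI1, 0.351, 0.739, 0.538 and 0.648 for CAKI2 and A498, 0.286, 0.665, 0.473 and 0.573 for CAKI2 and CAKI1, and 0.296, 0.681, 0.467 and 0.578 for A498 and CAKI1.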

Other observations

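The lists and tests in this part were all drawn up after the results had been seen, 11 lists in all, and the genes were named after their values were seen. The camera and fry p-values below are adjusted over these 11 lists alone. They do not allow for that choice, so they describe the lists and do not test them. Genes for entry into and traffic through the secretory pathway rose alongside the unfolded protein response. Of 26 genes of N-glycosylation and the translocon, 17 rose and 0 fell in limma (19 and 1 adjusted over the list alone). The median was 0.52 (camera adjusted p = 1.15e-08, and adjusted p = 0.127 with an estimated correlation). GFPT1 (1.51), which makes the sugar precursor, and the translocon gene SEC61A1 (1.32) were among the highest. Of 27 genes of COPII, COPI and Golgi traffic, 17 rose and 0 fell (17 and 1 adjusted over the list alone). The median was 0.38 (adjusted p = 4.19e-06, and adjusted p = 0.222 with an estimated correlation), and GOLGB1 (1.40) and SEC24A (1.04) led. Of 15 cytosolic tRNA synthetases 6 rose and 0 fell (adjusted p = 0.00164, and adjusted p = 0.392 with an estimated correlation), led by WARS1 (1.62). WARS1, GARS1 and SARS1, which rose, and AARS1, which did not pass, are also on the PERK branch list, so the lists overlap. Among 18 KLF and AP-1 family factors 9 rose and 1 fell (adjusted p = 4.47e-05, and adjusted p = 0.127 with an estimated correlation). KLF4 (2.54) and MAFF (1.95) were highest and KLF12 (-0.65) fell.

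Of 18 genes of homologous recombination and the Fanconi pathway, 14 fell and 0 rose (14 and 2 adjusted over the list alone), with a median of -0.99. Camera in limma gave adjusted p = 4.19e-06, and adjusted p = 0.134 with an estimated correlation. RMI2 (-1.74), BRIP1 (-1.71) and EXO1 (-1.58) were lowest. Of 20 genes of the actin cytoskeleton, 10 fell and 1 rose, with a median of -0.49 (adjusted p = 0.000751, and adjusted p = 0.127 with an estimated correlation). ACTN4 (-0.98) and VCL (-0.95) fell, ANXA1 (0.94) rose, and ACTB, whose 3′ to 5′ ratio moved with treatment, is on this list. Mitochondrial ribosomal proteins had 7 of 25 lower and 0 higher (adjusted p = 0.0111, and adjusted p = 0.392 with an estimated correlation). Proteasome subunits had 4 of 27 lower and 0 higher (3 and 0 adjusted over the list alone), with a median of -0.10. Camera gave adjusted p = 0.0387, and adjusted p = 0.45 with an estimated correlation, and fry did not pass (adjusted p = 0.0629). The median lay at percentile 23.28 of matched random lists and was above 0 in ACHN (0.02), so a fall of the list is uncertain. A list of 8 histone genes, with 3 higher and 1 lower, did not pass (adjusted p = 0.169); the lower was H2AZ1 (-0.83), which encodes a replication-independent variant.

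Transcripts that host small nucleolar RNAs were higher: EPB41L4A-AS1 (2.30), SNHG32 (1.98), ZFAS1 (1.95) and SNHG17 (1.75) rose, while GAS5 had 0.12 (limma adjusted p = 0.669). The list of 5 passed camera (adjusted p = 2.53e-05, and adjusted p = 0.127 with an estimated correlation). Such transcripts are known targets of nonsense-mediated decay, and a weaker decay may raise them, which is a hypothesis. The list's median lay at percentile 100 of matched random lists in the line where it was lowest, but GAS5 did not follow and the list was drawn up after some hosts had been seen to rise, so this hypothesis remains open. Of 4 known substrates of IRE1-dependent decay, BLOC1S1 (-1.03) and SPARC (-0.85) fell, and HGSNAT (-0.24) and COL6A1 (-0.20) did not pass (list adjusted p = 0.0285, and adjusted p = 0.192 with an estimated correlation). That IRE1-dependent decay could lower them is a hypothesis too, but the list's median reached percentile 14.69 in ACHN, and 4 genes are too few to decide. The bounds for judging both hypotheses were rewritten after their values had been seen: by the first bounds the former would have been taken as supported and the latter as opposed, and both were left open because the lists are small and drawn up late.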
